A study of Mus musculus with 2 samples.

How the data were processed

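Single-cell RNA sequencing of CD45+ sorted cells from subcutaneous B16F10-OVA tumours was analysed for mice injected with PBS and mice injected with UDSP-Hep. About 10000 cells per group were loaded, per the labels' protocols, and each group gave 1 library from 3 tumours. The deposited values were raw UMI counts per gene and barcode for 32285 genes, made with Cell Ranger 7.0.0, per the file headers and the submitters' processing notes. The deposited gene names and barcodes accompanied the counts. The genome build was mm10, per the submitters' processing notes, which also name Seurat without a version or a role. Which barcodes the authors had taken out is not given in the sources used here. The smallest barcode total was 500 UMIs in each library. Gene coordinates were taken from GENCODE release M21 on GRCm38, the assembly that mm10 names, and matched by gene identifier.

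Cells were kept with at least 200 detected genes, at least 500 UMIs and under 10% mitochondrial UMIs. These filters removed 245 PBS and 197 UDSP-Hep barcodes. Doublets were scored per library with Scrublet as provided by scanpy, on barcodes with at least 200 genes, at least 500 UMIs and under 20% mitochondrial UMIs. Its own threshold marked 0.041% and 0.051% of these barcodes, under the preset minimum of 0.5%, so the highest scores at 0.8% per 1000 barcodes were taken out instead, which were 417 and 480 of the barcodes that passed the other filters. The kept cells had 66056571 and 55906161 UMIs in all, and median depths of 7865 and 5482 UMIs.

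Both libraries were clustered together without integration, on log-normalized counts of 2000 variable genes, with 30 principal components, 15 neighbours and Leiden resolution 1.0. T and NK clusters and mononuclear phagocyte and dendritic clusters were clustered once more the same way. This gave 39 clusters, named from markers of 26 cell types. A name needed at least 3 markers, each at a log2 ratio of at least 1 over other cells and at least 10 CPM with 10 CPM added to both sides, a lead of 0.5 over the next name, and a mean doublet score of at most 0.1. It also needed no more markers of another type than of its own among the top 10 genes, and a median UMI count of at least the library's divided by 3 unless its own markers led. In a cluster with Cd3e, Cd3d and Cd3g all at a log2 ratio of at least 1, the innate names NK and ILC2 were not allowed. These naming thresholds were set after the data were seen. Clusters M0, M2 and M5 had no finer name and were placed in macrophages and monocytes from their markers against cells outside the phagocytes, and 8 clusters stayed unnamed. The names are rebuilt here and are not the authors'.

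There were no replicates, so no test of a difference between the groups was made and no p-value is given. A share of cells has an exact binomial (Clopper-Pearson) interval, and a ratio of shares a Katz log interval. Within a class, UMIs were summed per library and given as CPM of all UMIs of the class, with exact Poisson intervals, and the ratio of CPM has an exact conditional binomial interval. The ratio of median mitochondrial shares in the closing part has an interval from 1000 bootstrap draws of cells. All other intervals cover counting error only, and all are at 95%. The deeper classes therefore have the narrower intervals: macrophages and monocytes had 35004469 and 23564615 summed UMIs, neutrophils 163851 and 2083019.

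For gene lists the median log2 ratio of CPM was taken over members with at least 20 summed UMIs, with an interval from 1000 Poisson draws, and set beside 10000 random lists of the same size matched on mean CPM in 20 bins, as a description of these libraries. The 20 lists were type I interferon response, interferon-gamma response, MHC class I presentation, MHC class II presentation, dendritic cell maturation, cytotoxic effector, checkpoint and exhaustion, naive and memory, Treg effector, pro-inflammatory myeloid, alternatively activated macrophage, lipid handling and lysosome, chemokines, neutrophil granule and maturity, tumour neutrophil activation, glycolysis, oxidative phosphorylation, hypoxia, proliferation, and dissociation and early stress. Lists were computed in classes with at least 50 cells in each library. Ratios relative to the median gene used median-of-ratios scaling.

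Named genes were chosen in classes with at least 100 cells in each library, among genes with at least 50 summed UMIs and at least 50 CPM in the library where they were higher. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and T cell receptor segment genes, Xist, Tsix, Y-linked genes and markers of other classes were left out. Genes were ranked by the bound of the ratio's interval nearest to equality, and the 10 highest and 10 lowest were named in the 4 classes with the most cells and 5 of each in Treg. List members are named as examples. The groups, markers, lists, rule for named genes, filters and 14 alternatives were chosen before the data were examined, and the thresholds for naming clusters and 5 further alternatives after.

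Alternatives chosen before the data were examined were mitochondrial limits of 5% and 20%, a minimum of 500 genes, doublets kept, Leiden resolutions of 0.5 and 2.0, each library clustered on its own, median-of-ratios and TMM scaling, every cell weighed the same, every cell thinned to 1000 UMIs, list members with at least 100 UMIs or with any UMI, and a naming minimum of 200 UMIs. The added ones left granulocytes, or granulocytes and NK cells, out of the total of the shares, included the unnamed phagocyte cluster M3, left out the heat-shock cluster M5, or gave every cluster with at least 30 cells in each library the same weight. Weighing clusters the same left out M5 in macrophages and monocytes and M6 in dendritic cells, which had too few cells. Thinning left out 9 and 8 CD8 T cells, 9 and 20 NK cells, and 3 and 63 neutrophils.

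The ratio and its interval were tested on simulated counts with 200 genes changed. The counts were Poisson draws, the model that the interval assumes, so this checked the calculation. Variation between cells, clusters or tumours was not simulated. Of 11235 genes simulated for macrophages and monocytes, 95.1% had an interval that held the true ratio, and 96.0% of genes changed 2-fold and 100% of those changed 4-fold were recovered. The same values were 95.5%, 93.3% and 100% of 9304 genes for CD8 T cells, and 95.7%, 95.8% and 97.1% of 8746 for NK cells. For dendritic cells they were 95.7%, 96.2% and 99.0% of 9735, and for Treg 96.0%, 94.3% and 100% of 7556. The tools were Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3 and, for TMM factors of the deposited counts, edgeR 4.0.16.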

Results

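CD45+ leukocytes from mouse tumours were profiled by droplet single-cell RNA sequencing on the 10x Genomics platform. Each captured transcript carried a cell barcode and a unique molecular identifier (UMI), so that RNA molecules were counted per cell. CD45 is a surface protein of leukocytes, and the cells had been sorted on it. The tumours were subcutaneous grafts of B16F10-OVA, a mouse melanoma line that expresses ovalbumin as a model antigen. The mice had received injections of PBS, a saline buffer, or of UDSP-Hep, which the labels name without describing. The injections were given at days 10, 12, 14 and 16, and tumours were taken at day 19. In each group 3 tumours went into 1 library, and no file used here maps cells to tumours, so each group had 1 library and no replicate.

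The PBS library held 7379 barcodes and 74685827 UMIs, with a median of 7890 UMIs and 2472 genes per barcode. The UDSP-Hep library held 7872 barcodes and 64241224 UMIs, with a median of 5641 UMIs and 2165.5 genes. After filtering, 6717 PBS cells and 7195 UDSP-Hep cells remained. All ratios are UDSP-Hep over PBS. Values given in pairs are PBS first, and intervals are 95% intervals that cover counting error only. None of the differences has a replicate check.

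The first comparison asked which leukocytes made up each library. Neutrophils, short-lived granulocytes, were 0.834% (0.630 to 1.08%) of PBS cells and 11.7% (10.97 to 12.5%) of UDSP-Hep cells, a ratio of 14.0 (10.7 to 18.4). NK cells, innate cytotoxic lymphocytes, were 6.28% (5.71 to 6.89%) and 19.2% (18.3 to 20.1%), a ratio of 3.05 (2.75 to 3.38). Macrophages and monocytes were the largest class in both libraries, at 53.5% (52.2 to 54.7%) and 33.8% (32.7 to 34.9%), a ratio of 0.631 (0.607 to 0.657). Dendritic cells, which present antigen to T cells, were 9.98% (9.27 to 10.7%) and 4.49% (4.02 to 4.99%), a ratio of 0.450 (0.396 to 0.512). Brackets after a share give its exact binomial interval.

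CD8 T cells were 7.995% (7.36 to 8.67%) and 6.62% (6.05 to 7.22%), a ratio of 0.828 (0.735 to 0.932). Regulatory T cells (Treg), which restrain immune responses, were 3.05% (2.65 to 3.49%) and 3.88% (3.44 to 4.35%), a ratio of 1.27 (1.06 to 1.52). The number of CD8 T cells per Treg was 2.62 in the PBS library and 1.71 in the UDSP-Hep library, a ratio of 0.651 (0.524 to 0.810). Clusters T10 and T13, left unnamed by thresholds set after seeing the data, are in neither count. Treg markers scored highest in T10 (94 and 93 cells), with CD8 T markers close behind and a mean doublet score over 0.1. CD8 T markers scored highest in T13 (44 and 60 cells), with CD4 T markers close behind. The ratio therefore depends on that naming. Other CD4 T cells were 1.24% and 2.07%, a ratio of 1.68 (1.28 to 2.19). Gamma-delta T cells numbered 42 and 12, a ratio of shares of 0.267 (0.141 to 0.506). Cluster T3, left unnamed by thresholds set after seeing the data although gamma-delta T markers scored highest in it with CD8 T markers close behind, held 254 and 327 cells. B cells were 0.774% and 0.959%, and the interval of their ratio, 1.24 (0.866 to 1.77), included equality.

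Eosinophils numbered 8 and 133 cells, or 0.119% (0.0514 to 0.235%) and 1.85% (1.55 to 2.19%), a ratio of 15.5 (7.61 to 31.7). Their median UMI counts, 597 and 728, lay near the smallest barcode total of 500 UMIs in both libraries, so that minimum can set how many were seen. Neutrophils had medians of 2259.5 and 2323 UMIs. Basophils were 1.76% and 0.862%, a ratio of 0.491 (0.361 to 0.666), and plasmacytoid dendritic cells were 1.22% and 0.445%, a ratio of 0.364 (0.243 to 0.547). Within the dendritic cells, cDC1, a subset known for cross-presentation to CD8 T cells, were 1.46% and 0.320% (ratio 0.219, 0.139 to 0.345). The shares of cDC2 were 5.73% and 3.36% (ratio 0.587, 0.501 to 0.687) and those of mature dendritic cells 2.78% and 0.806% (ratio 0.290, 0.216 to 0.388). Cluster M18, where mature dendritic cell markers scored highest with macrophage markers close behind, went the other way. It held 67 and 186 cells (ratio 2.59, 1.96 to 3.42). Thresholds set after seeing the data left it unnamed, also for its mean doublet score. Nonclassical monocytes, a vessel-patrolling subset, were 3.71% and 7.92% (ratio 2.14, 1.85 to 2.47). Clusters named monocyte were 16.9% and 15.3% (ratio 0.907, 0.841 to 0.979) and clusters named macrophage 12.0% and 7.62% (ratio 0.634, 0.572 to 0.703). Clusters M0 and M5, where monocyte markers scored highest, were left unnamed by thresholds set after seeing the data and are in neither share. They held 373 and 56 cells and 416 and 8 cells, so the monocyte ratio depends on that naming.

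**Figure D1:**
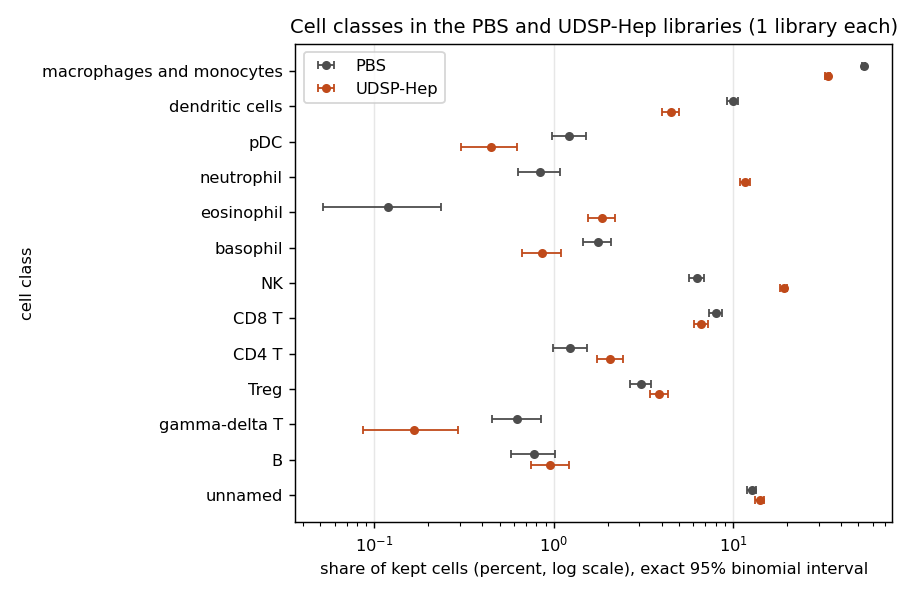
Share of kept cells in each cell class, in percent on a log axis, for the PBS and the UDSP-Hep library (1 library each), with bars for the exact 95% binomial interval. Neutrophils stand at 0.834% and 11.7%, NK cells at 6.28% and 19.2%, and macrophages and monocytes at 53.5% and 33.8%.

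The shares are of cells sorted on CD45, from libraries of different median depth and with a UMI minimum, and clusters left unnamed by thresholds set after seeing the data held 12.7% and 14.1% of cells. The ratio for CD8 T cells was 1.13 with granulocytes and NK cells left out of the total, an alternative chosen after seeing the data, and 0.391 at a Leiden resolution of 0.5, where CD8 T cells per Treg had a ratio of 0.317. The ratio for gamma-delta T cells was 1.04 with doublets kept and 1.07 at a resolution of 2.0. With 1 library per group, a cluster mostly of 1 library may be that library and not a cell type.

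The second comparison asked how expression differed within each class. A gene of a list counted as higher or lower where its ratio was at least 1.5, or at most the inverse of that, with an interval that excluded equality. Hspa1a and Hspa1b, which encode inducible HSP70 chaperones, were lower in the UDSP-Hep library in all 5 classes in which genes were ranked. In macrophages and monocytes Hspa1a stood at 1005 and 78.0 CPM (CPM is the usual scaled count, here of all UMIs of the class) and Hspa1b at 1554 and 141 CPM. The ratios for Hspa1a and Hspa1b were 0.0952 and 0.122 in NK cells, 0.173 and 0.138 in Treg, 0.249 and 0.283 in CD8 T cells, and 0.345 and 0.335 in dendritic cells. In classes where genes were not ranked, the ratio of both genes summed was 0.00770 (0.00398 to 0.0135) in basophils, 0.148 (0.119 to 0.183) in other CD4 T cells and 0.0416 (0.00841 to 0.126) in B cells. The B cell value rests on 80 and 3 UMIs. Summed markers in B cells were 16.7 and 3089 CPM for neutrophils and 4754 and 337 CPM for plasma cells, so the class differed in make-up. In neutrophils Hspa1b was higher, at 250.2 and 473 CPM (ratio 1.89, 1.38 to 2.65), and Hspa1a lower, at 469.9 and 106 CPM (0.225, 0.173 to 0.295). Hspa1a (ENSMUSG00000091971, chromosome 17 from 34969190 to 34972156) and Hspa1b (ENSMUSG00000090877, chromosome 17 from 34956436 to 34959238) are protein-coding genes on the minus strand of GRCm38. They are near-identical copies, so the split of counts between them is uncertain, and summed they stood at 720.2 and 579 CPM in neutrophils (ratio 0.803, 0.664 to 0.979). In macrophages and monocytes their CPM log2 ratios were -3.69 and -3.47. They were -2.79 and -2.52 without M5, the cluster led by heat-shock genes. With clusters weighed the same they were -2.26 and -1.90, and M5 was left out there too, for too few cells. Both alternatives were chosen after seeing the data. Over the alternatives, the log2 ratios of Hspa1a and Hspa1b ranged from -3.09 to -1.43 and from -2.66 to -1.49 in CD8 T cells, from -3.69 to -1.72 and from -3.60 to -1.78 in Treg, all below equality.

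**Figure D2:**
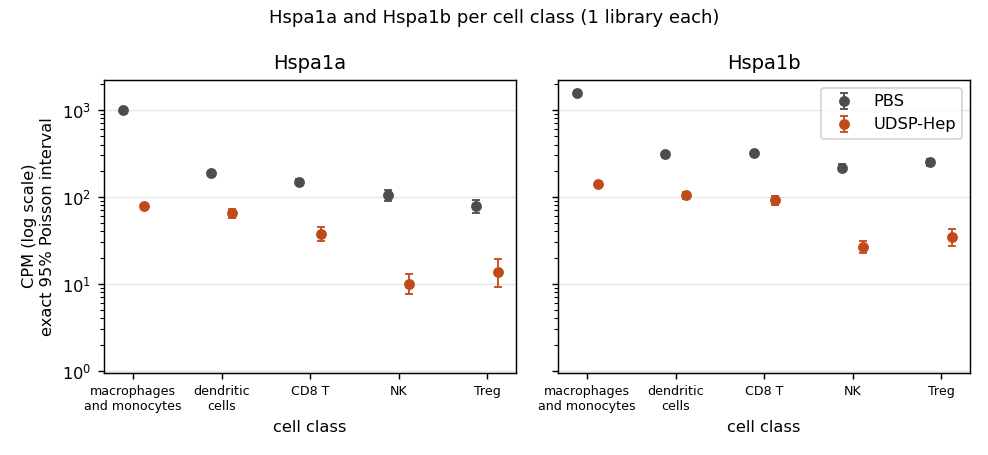
Hspa1a and Hspa1b in CPM on a log axis in each of 5 cell classes, for the PBS and the UDSP-Hep library (1 library each), with exact 95% Poisson intervals for counting error. In macrophages and monocytes Hspa1a stands at 1005 and 78.0 CPM and Hspa1b at 1554 and 141 CPM.

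In CD8 T cells, which kill cells that display their antigen, naive and memory genes were higher and several checkpoint and exhaustion genes lower in the UDSP-Hep library. For naive and memory genes, of 13 measured, 11 counted as higher, 0 as lower and 2 as neither (median log2 ratio 0.97, 0.89 to 1.10). Tcf7, a transcription factor of stem-like T cells, stood at 89.8 and 224 CPM (ratio 2.49, 2.23 to 2.79), the interleukin-7 receptor gene Il7r at 116 and 287 CPM (2.47, 2.24 to 2.73), and S1pr1, which encodes a receptor for tissue egress, at 42.6 and 116 CPM (2.73, 2.33 to 3.21). For checkpoint and exhaustion genes, of 15 measured, 1 counted as higher, 4 as lower and 10 as neither (median -0.44, -0.57 to -0.34). Tox, a transcription factor of exhausted T cells (ENSMUSG00000041272, chromosome 4 from 6686353 to 6991557), stood at 322 and 126 CPM (ratio 0.389, 0.350 to 0.433), Pdcd1, which encodes PD-1, at 412 and 263 CPM (0.638, 0.591 to 0.689), and Havcr2, which encodes TIM-3, at 143 and 84.0 CPM (0.589, 0.513 to 0.674). Nr4a3 was the higher member, at 66.9 and 187 CPM, and Ctla4 stood at 342 and 496 CPM.

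For cytotoxic effector genes in CD8 T cells, of 20 measured, 9 counted as higher, 0 as lower and 11 as neither (median 0.51, 0.47 to 0.62). The granzyme gene Gzma stood at 593 and 1082 CPM (ratio 1.83, 1.74 to 1.91), Ifng, which encodes interferon gamma, at 271 and 427 CPM (1.57, 1.47 to 1.69), and Klrg1 at 8.78 and 34.5 CPM (3.93, 2.82 to 5.54). Gzmb, at 928 and 974 CPM, and the perforin gene Prf1, at 449 and 409 CPM, were neither. For proliferation genes, of 20 measured, 0 counted as higher, 10 as lower and 10 as neither (median -0.58, -0.65 to -0.53), and Mki67 stood at 142 and 102 CPM. For interferon-gamma response genes, of 20 measured, 10 counted as higher, 0 as lower and 10 as neither (median 0.81, 0.59 to 0.87), with Cd274, which encodes PD-L1, at 35.5 and 88.7 CPM. Of 10000 random lists of the same size matched on expression, 10000 had a median below that of the naive and memory list and 10000 below that of the cytotoxic effector list. All 10000 had a median above that of the checkpoint and exhaustion list, and all 10000 above that of the proliferation list. The medians were -0.38 for glycolysis and -0.26 for oxidative phosphorylation genes. For dissociation and early stress genes, of 20 measured, 11 counted as higher, 4 as lower and 5 as neither (median 0.83, 0.67 to 0.93), with immediate early genes such as Fos (ratio 2.49) higher and the heat-shock genes Hspa1a, Hspa1b, Hsp90aa1 and Hsph1 lower.

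The 10 genes furthest above equality in CD8 T cells included Tpm3-rs7 (5.47 and 71.9 CPM), the granzyme gene Gzmc (101 and 464 CPM, ratio 4.61, 4.20 to 5.07), the phosphodiesterase gene Pde2a (17.2 and 89.0 CPM), the transcription factor gene Klf3 (33.0 and 148 CPM), the chemokine gene Xcl1 (86.3 and 283 CPM), Gzme, Lmna and Gm26532. Counts of the similar genes Gzmc (ENSMUSG00000079186, chromosome 14 from 56231441 to 56234656) and Gzme are uncertain, as are those of Tpm3-rs7, which resembles Tpm3. The others were the myeloid genes Il1b, at 21.9 and 79.8 CPM, and Cxcl2, at 13.8 and 51.9 CPM. Il1b was at 1.89% and 3.40% and Cxcl2 at 1.83% and 6.54% of its level in macrophages and monocytes, so RNA of other cells was not excluded for either. The log2 ratio of Il1b was 3.80 with every cell thinned to 1000 UMIs in place of 1.87. Summed neutrophil markers in CD8 T cells were 6.46 and 53.6 CPM. The genes furthest below were Hspa1a, Hspa1b, Hist1h2ae, Tox, Gm42031, Hist1h1b, the dUTPase gene Dut (452 and 211 CPM), Ifi27l2a (974 and 499 CPM), Adap1 and S100a4 (1428 and 764 CPM). Counts of the histone genes are uncertain because similar copies exist.

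**Figure D3:**
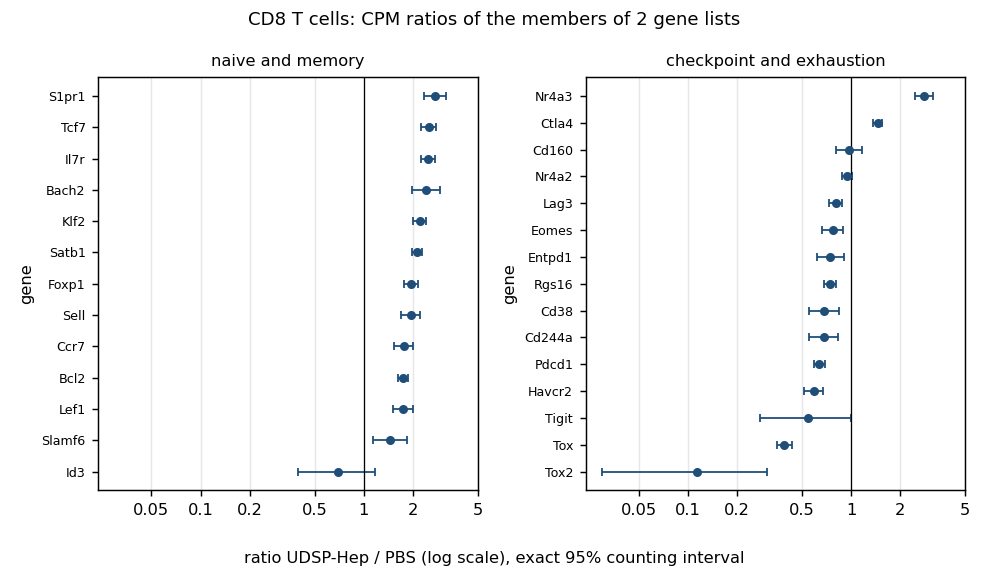
Ratio of CPM (UDSP-Hep over PBS, log axis) in CD8 T cells for each measured gene of the naive and memory list and of the checkpoint and exhaustion list, 1 library per group, with exact 95% counting intervals. Tcf7 stands at 2.49, S1pr1 at 2.73 and Tox at 0.389.

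Different clusters held most CD8 T cells of each library. Cluster T1, whose leading genes included Pdcd1 and Tox, held 247 and 107 cells. T0, with the proliferation genes Pclaf and Top2a among its leading genes, held 121 and 44. T11, whose leading genes included Gzmk, Ccl5 and S1pr1, held 79 and 247. T2, led by Tcf7 and Lef1, held 90 and 78. The median UMI counts of the class were 8250 and 4966. With every cluster weighed the same, an alternative chosen after seeing the data, the median for naive and memory genes was 0.20. The log2 ratios of Klf3 and Pde2a were 0.70 and 1.24 there. The medians for checkpoint and exhaustion genes and for proliferation genes were also nearer equality in that weighing. The proliferation median was 0.051 at a Leiden resolution of 0.5, -1.23 with every cell weighed the same, -1.36 with every cell thinned to 1000 UMIs and -3.96 with each library clustered on its own. In that last setting the naive and memory median was 1.65, and Gzmc and Gzme turned to log2 ratios of -0.57 and -0.83.

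In NK cells, cytotoxic effector genes stood at similar levels in both libraries: of 17 measured, 1 counted as higher, 0 as lower and 16 as neither (median log2 ratio 0.079, -0.0039 to 0.16; 7638 of 10000 random lists lay below). Prf1 stood at 1206 and 1372 CPM, Gzmb at 2059 and 1612 CPM and Ifng at 170.4 and 116 CPM. The higher member was the chemokine receptor gene Cx3cr1, at 34.8 and 62.4 CPM (ratio 1.79, 1.38 to 2.37). Among the 10 furthest above equality were the transcription factor genes Junb, Nr4a2 and Nr4a3. Junb stood at 913 and 1869 CPM (ratio 2.05, 1.95 to 2.16), Nr4a2 at 234 and 497 CPM (2.12, 1.92 to 2.35) and Nr4a3 at 64.9 and 156 CPM (2.40, 1.99 to 2.92). Cebpb, Sik1, Dgkz, Gm26532 and Tpm3-rs7 were the others, with the myeloid genes Cxcl2 and Il1b. Cxcl2 reached 1.55% and 8.72% and Il1b 1.55% and 4.07% of its level in macrophages and monocytes, and summed neutrophil markers in NK cells were 12.7 and 61.2 CPM, so RNA of other cells was not excluded for either gene. Below equality, after Hspa1a and Hspa1b, were S100a1, the cell-cycle kinase gene Cdk6 (154 and 69.8 CPM), the transcription factor gene Jun (269 and 143 CPM), Selenoh, the co-chaperone gene Dnajb1 (90.2 and 48.2 CPM), AY036118, Hist1h1e and Zfp512. Checkpoint and exhaustion genes had a median of 0.35, and glycolysis genes -0.34. Dissociation and early stress genes had a median of 0.46. Cluster T4 held 157 and 656 NK cells, T5 held 117 and 95 and T6 held 148 and 628.

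In Treg, Areg, which encodes the growth factor amphiregulin, was higher in the UDSP-Hep library, at 254 and 872 CPM (ratio 3.44, 3.09 to 3.83), and so was the cytokine gene Il10, at 174 and 479 CPM (2.75, 2.42 to 3.15). Of the Treg effector genes, 4 of 19 were higher, 0 lower and 15 neither (median log2 ratio 0.27, 0.20 to 0.38), and 10000 of 10000 random lists lay below. Il2ra (1.76, 1.65 to 1.87) and Lrrc32 (1.72, 1.45 to 2.05) were also higher, while Foxp3, the lineage transcription factor, stood at 629 and 669 CPM. The 5 genes furthest above equality were Tpm3-rs7, the immediate early genes Fosb (18.7 and 103 CPM) and Fos (118 and 388 CPM), Gm17767 and the macrophage chemokine gene Ccl24 (22.3 and 79.5 CPM, or 0.855% and 16.0% of the levels in macrophages and monocytes). Summed markers in Treg were 6.64 and 47.4 CPM for neutrophils and 75.5 and 143 CPM for macrophages. The 5 furthest below were Hspa1b, Hspa1a, Gm42031, the proenkephalin gene Penk (177 and 81.8 CPM) and the chemokine gene Ccl5 (700.4 and 358 CPM). The medians were -0.30 for proliferation, -0.24 for glycolysis and 0.41 for dissociation and early stress genes. Cluster T7 held 169 and 232 Treg and T12 held 36 and 47. With each library clustered on its own the Treg effector median was -0.29 and the proliferation median 0.23. With every cell thinned to 1000 UMIs, Ccl24 and Penk had log2 ratios of -0.66 and 0.0079. Ccl24 also turned to -1.72 at a Leiden resolution of 0.5, -1.90 with each library clustered on its own and -0.37 with every cell weighed the same.

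In macrophages and monocytes, genes of alternative activation and of hypoxia were lower in the UDSP-Hep library. The median gene of this class had a log2 ratio of 0.12, and the ratios and medians given for the class are relative to it (median-of-ratios scaling), beside CPM as counted. For alternatively activated macrophage genes, of 20 measured, 1 counted as higher, 12 as lower and 7 as neither (relative median log2 ratio -0.70, -0.81 to -0.63). Arg1, the arginase of alternatively activated macrophages, stood at 2045 and 639 CPM (relative ratio 0.287, 0.282 to 0.292), the mannose receptor gene Mrc1 at 792 and 337 CPM (0.391, 0.381 to 0.401), and Spp1, which encodes osteopontin, at 581 and 183 CPM (0.289, 0.280 to 0.299). Gpnmb was the higher member, at 77.5 and 192 CPM (2.28, 2.17 to 2.39).

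For hypoxia genes in this class, of 16 measured, 0 counted as higher, 12 as lower and 4 as neither (relative median -1.14, -1.25 to -1.11). The adrenomedullin gene Adm stood at 37.0 and 3.78 CPM (relative ratio 0.0939, 0.0749 to 0.116), Ndrg1 at 323 and 116 CPM (0.330, 0.316 to 0.344) and the glucose transporter gene Slc2a1 at 319.9 and 150.4 CPM (0.432, 0.416 to 0.449), while Vegfa, which encodes a growth factor of blood vessels, stood at 268 and 274 CPM. Glycolysis genes had a relative median of -0.64, with 11 of 16 lower, and proliferation genes of -0.81, with 14 of 20 lower. Oxidative phosphorylation genes were at -0.16. Lipid handling and lysosome genes were at -0.048 and dissociation and early stress genes at -0.070, both of which flip in sign from the CPM medians of 0.074 and 0.052.

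For pro-inflammatory myeloid genes in this class, of 20 measured, 4 counted as higher, 0 as lower and 16 as neither (relative median 0.14, 0.040 to 0.18). Il1b, which encodes interleukin-1 beta (ENSMUSG00000027398, chromosome 2 from 129364570 to 129371139), stood at 1155 and 2352 CPM (relative ratio 1.87, 1.85 to 1.90), and the neutrophil chemoattractant gene Cxcl1 at 9.77 and 26.4 CPM (2.48, 2.17 to 2.84). Summed neutrophil markers in the class were 170.3 and 261 CPM. For type I interferon response genes, of 25 measured, 2 counted as higher, 9 as lower and 14 as neither (relative median -0.42, -0.48 to -0.36). Rsad2, which encodes the antiviral protein viperin, stood at 509 and 323 CPM (0.584, 0.568 to 0.600). Interferon-gamma response genes had a relative median of 0.13, with 2 of 24 higher. MHC class II presentation genes had 0.15 and MHC class I presentation genes 0.24, each with 0 higher and 0 lower. H2-Aa, an MHC class II gene, stood at 2194 and 3047 CPM. By CPM, all 10000 random lists lay above the alternatively activated list and all 10000 above the type I interferon list. The lists below were 9933 for pro-inflammatory, 9969 for interferon-gamma and 9898 for MHC class II genes.

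**Figure D4:**
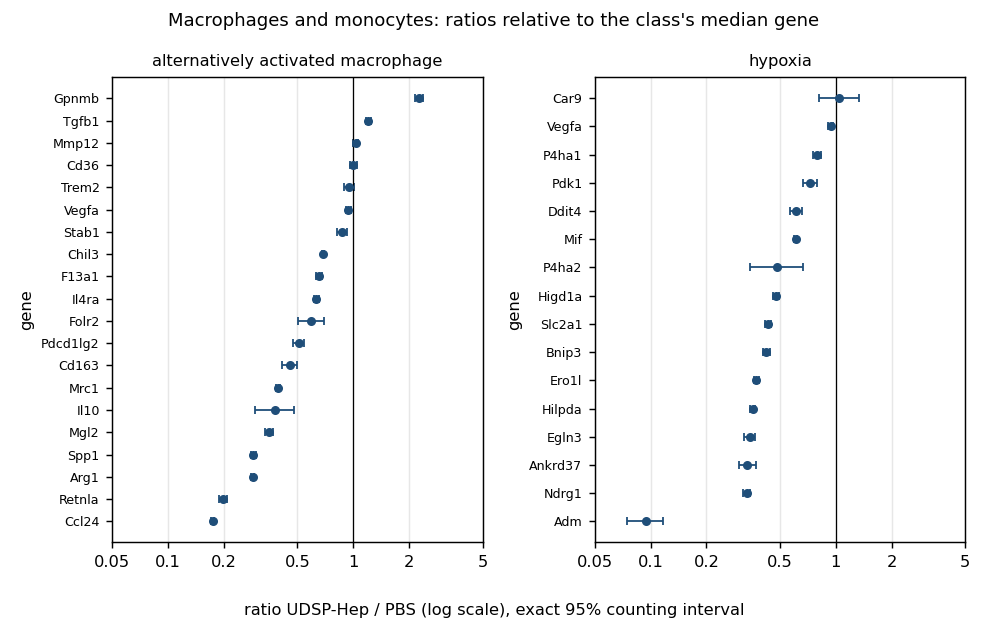
Ratio relative to the median gene (UDSP-Hep over PBS, log axis, median-of-ratios scaling) in macrophages and monocytes for each measured gene of the alternatively activated macrophage list and of the hypoxia list, 1 library per group, with exact 95% counting intervals. Arg1 stands at 0.287, Gpnmb at 2.28 and Adm at 0.0939.

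The 10 genes furthest below equality in macrophages and monocytes were Hspa1a, Hspa1b, the collagenase gene Mmp13 (159 and 23.5 CPM), Ccl24, which encodes an eosinophil chemoattractant (2614 and 497 CPM, relative ratio 0.175, 0.171 to 0.178), Retnla, a marker of alternative activation (352 and 75.7 CPM, 0.198, 0.188 to 0.208), the growth factor gene Hbegf (175 and 39.1 CPM), the metallothionein gene Mt2, Dmkn, Timp1 and Ccl7 (1688 and 521 CPM). Ccl24 is ENSMUSG00000004814, chromosome 5 from 135569937 to 135573049, and Retnla is ENSMUSG00000061100, chromosome 16 from 48842551 to 48844461. For chemokines, of 19 measured, 5 counted as higher, 6 as lower and 8 as neither (relative median -0.24, -0.28 to -0.19). Their CPM median, -0.12, turned to 0.00014 with a mitochondrial limit of 5%, 0.0069 and 0.0056 at Leiden resolutions of 0.5 and 2.0, and 0.044 with every cluster weighed the same. The monocyte chemoattractant genes Ccl2, Ccl7, Ccl8 and Ccl12 had relative ratios of 0.387, 0.284, 0.389 and 0.343, with the split between these similar genes uncertain. Furthest above equality were Tpm3-rs7 (8.60 and 73.4 CPM), Gm15056, Pglyrp1, Smpdl3b, the formyl peptide receptor gene Fpr2 (29.9 and 101 CPM, 3.10, 2.88 to 3.33), Jaml, Ly6i, Adgre4, Ace (62.4 and 194 CPM, 2.86, 2.72 to 3.02) and Tmcc3. Ace (ENSMUSG00000020681, chromosome 11 from 105967945 to 105989964) is a marker of nonclassical monocytes, whose share was higher.

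The clusters of macrophages and monocytes were split unevenly between the libraries. Cluster M2, whose leading genes included the hypoxia genes Ero1l, Egln3, Ndrg1, Adm and Hilpda, held 612 and 145 cells. Rsad2 was among its leading genes too. M5, led by Hspa1a and Hspa1b, held 416 and 8. M7, whose leading genes included the type I interferon genes Ifit1, Ifit2 and Ifit3, held 264 and 156. Clusters M0 and M14 held 373 and 56 cells and 270 and 36 cells, whereas M12 and M9 held 158 and 479 cells and 452 and 608 cells. With every cluster but M5 weighed the same, the CPM median of the alternatively activated genes was 0.019 in place of -0.58. This alternative was chosen after seeing the data, and M5 had too few cells for it. In it the CPM log2 ratios of Ccl24, Retnla and Ace were -0.79, -0.41 and 0.40, and the type I interferon median was also nearer equality. Cluster M3, left unnamed by thresholds set after seeing the data although macrophage markers scored highest in it, held 5.35% and 2.63% of cells, and with it in the class the CPM log2 ratio of Mmp13 was -1.76 in place of -2.76.

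In dendritic cells, pro-inflammatory genes were higher in the UDSP-Hep library: of 18 measured, 11 counted as higher, 0 as lower and 7 as neither (median log2 ratio 0.81, 0.70 to 0.88). Il1b stood at 710 and 1843 CPM (ratio 2.60, 2.52 to 2.68) and the chemokine gene Cxcl2 at 69.7 and 181 CPM (2.60, 2.35 to 2.88). Summed markers in these cells were 32.0 and 94.3 CPM for neutrophils, 331 and 498 CPM for macrophages and 2050 and 2878 CPM for monocytes. For dendritic cell maturation genes, of 17 measured, 2 counted as higher, 0 as lower and 15 as neither (median -0.085, -0.12 to 0.074): Il12b, which encodes a subunit of interleukin-12, stood at 38.5 and 69.0 CPM (1.79, 1.54 to 2.08) and the chemokine gene Ccl17 at 161 and 314 CPM (1.96, 1.82 to 2.10), while Ccr7, a receptor gene for migration to lymph nodes, stood at 791 and 629.9 CPM. Of MHC class I presentation genes, 1 of 16 counted as higher and 15 as neither (median 0.20, 0.13 to 0.22). The random lists below were 370 of 10000 for maturation and 9919 for MHC class I genes. Chemokines had a median of 0.46, hypoxia genes -0.30, dissociation and early stress genes 0.43 and proliferation genes -2.49.

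Other genes furthest above equality in dendritic cells were Tpm3-rs7, the transcriptional regulator gene Id3 (6.58 and 51.6 CPM, ratio 7.85, 5.97 to 10.4), Cd33, Tnfaip2 (66.5 and 228 CPM), Spon1, the pattern recognition receptor gene Tlr2 (33.7 and 105 CPM), Dusp2 and Rnd3. Furthest below were Top2a, Pclaf, Xcr1 (162 and 35.5 CPM, ratio 0.219, 0.185 to 0.258), Cadm1, Stmn1, Hspa1b, Hspa1a, Tlr3, Tnfrsf9 and Itgae. Xcr1 (ENSMUSG00000060509, chromosome 9 from 123852315 to 123862029), Cadm1 and Itgae are cDC1 markers. Cluster M6, named cDC1, held 98 and 23 cells, M8 300 and 166, M10 85 and 76 and M17 187 and 58. With the clusters M8, M10 and M17 weighed the same and M6 left out for too few cells, an alternative chosen after seeing the data, the proliferation median was 0.18 and the log2 ratios of Cadm1 and Xcr1 were 1.01 and -0.20. The maturation median was 0.18 there and 0.12 with each library clustered on its own, and Tnfrsf9 then had a log2 ratio of -0.11 in place of -1.60.

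Neutrophils, 56 and 842 cells, had higher levels of several activation genes in the UDSP-Hep library. Median-of-ratios scaling shifted their log2 ratios by -0.13 and TMM scaling by 0.084, and relative values are by the former. For tumour neutrophil activation genes, of 14 measured, 4 counted as higher, 1 as lower and 9 as neither (relative median 0.50, 0.093 to 0.60). The prostaglandin synthase gene Ptgs2 stood at 1941 and 3943 CPM (relative ratio 1.86, 1.66 to 2.08), the adhesion molecule gene Icam1 at 165 and 519.9 CPM (2.88, 1.97 to 4.39), the cytokine gene Tnf at 244 and 589 CPM (2.20, 1.61 to 3.10), and Vegfa, which was lower, at 598 and 339.9 CPM (0.519, 0.420 to 0.648). Summed markers in neutrophils were 2374 and 1268 CPM for monocytes and 592 and 332 CPM for macrophages, and Lyz2 stood at 2637 and 711 CPM. For neutrophil granule and maturity genes, of 14 measured, 4 counted as higher, 4 as lower and 6 as neither (relative median -0.13, -0.37 to 0.13), and the sign of this median flips to 0.083 under TMM scaling. The lipocalin gene Lcn2 stood at 793 and 2684 CPM (3.09, 2.60 to 3.71) and Retnlg at 1617 and 689 CPM (0.389, 0.341 to 0.446). By CPM, 9993 of 10000 random lists lay below the activation list and 5086 below the granule list. With each library clustered on its own, the CPM median of the granule list was -1.08 in place of -0.001.

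Within the finer groups, alternatively activated macrophage genes had a CPM median log2 ratio of -0.76, -0.92 to -0.66 in macrophages, with 13 of 20 lower, and of 0.20, 0.077 to 0.24 in monocytes. The macrophage median was -0.095 with at least 500 genes per cell and -0.0073 with every cluster weighed the same. The monocyte median turned to -1.11 with a mitochondrial limit of 5% and to -0.64 and -0.48 at Leiden resolutions of 0.5 and 2.0. It was also negative under every other alternative that clustered the cells anew. Hypoxia genes had -0.62, -0.71 to -0.55 in macrophages and 0.11, -0.0086 to 0.21 in monocytes. The monocyte median turned under several alternatives, among them -0.72 with doublets kept, -1.02 at a Leiden resolution of 0.5 and -1.72 with the 5% limit. These finer groups leave out clusters M0, M2 and M5 of the joint class. M2, whose leading genes included hypoxia genes, held 612 and 145 cells, so the finer medians do not split up that of the class. Mature dendritic cells had a pro-inflammatory median of 1.43, 1.15 to 1.59, with 11 of 16 genes higher. Summed markers of other cells in them were 77.4 and 696 CPM for macrophages and 10.7 and 177 CPM for neutrophils, and the myeloid gene Lyz2 stood at 33.4 and 639.5 CPM.

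**Figure D5:**
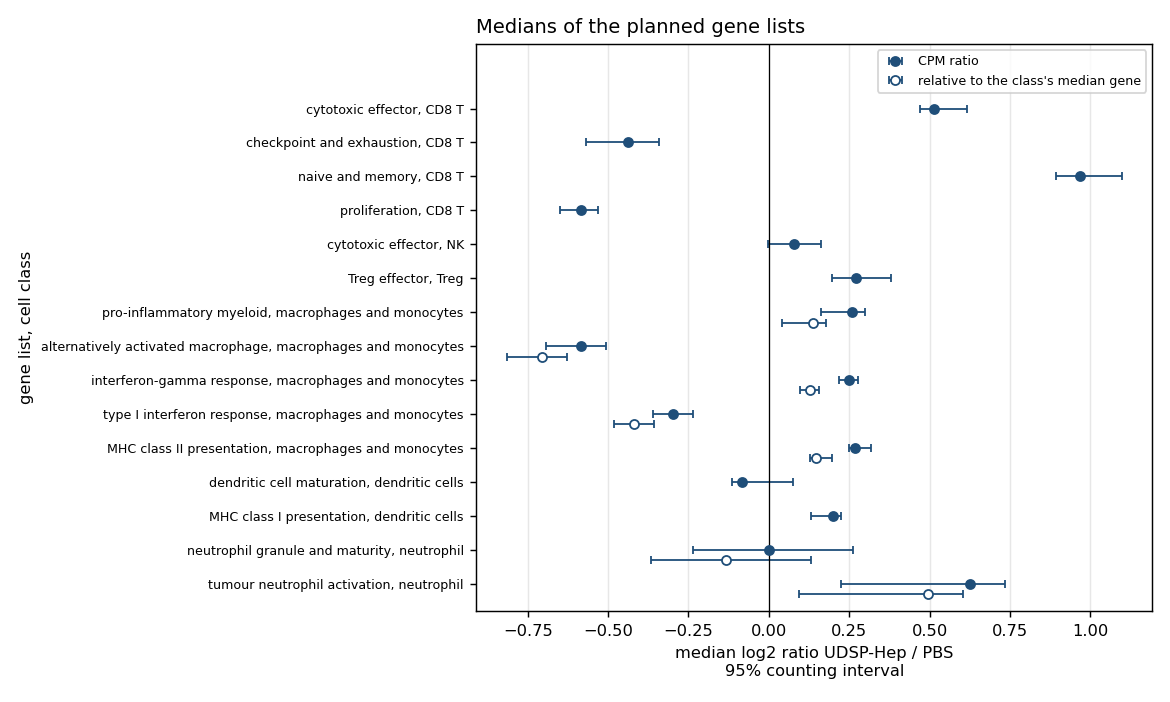
Median log2 ratio (UDSP-Hep over PBS) of the 15 main pairs of a gene list and a cell class, 1 library per group, with 95% counting intervals. Filled points are CPM ratios and open points are relative to the median gene (median-of-ratios scaling), and the CD8 T naive and memory list stands at 0.97, with the neutrophil granule list, whose sign flips between scalings, at -0.001 by CPM and -0.13 relative to the median gene.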

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

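The results in this part were picked out by fixed rules, and no test was run on them. MHC class II presentation genes went opposite ways in the 2 monocyte groups: their median log2 ratio was 0.65 in monocytes and -0.95 in nonclassical monocytes, and the difference was not tested. H2-Aa stood at 1180 and 2471 CPM in monocytes and 2003 and 1022 CPM in nonclassical monocytes. The monocyte median was -0.21 and 0.041 with mitochondrial limits of 5% and 20%, -0.068 with at least 500 genes per cell and -0.070 with doublets kept. The nonclassical median was 0.30 with each library clustered on its own, -0.22 at a Leiden resolution of 0.5 and -0.24 with every cluster weighed the same, the last chosen after seeing the data. The nonclassical monocytes were 158 and 479 cells of cluster M12 and 91 and 91 of M15.

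Melanoma markers were found in barcodes that the filters removed for reasons other than doublets, which no comparison used. They summed to 1888 CPM in 244 PBS barcodes (866 of 458601 UMIs) and to 764 CPM in 193 UDSP-Hep barcodes (272 of 356126 UMIs). The kept cells had 31.1 and 31.3 CPM, and a count of 0 in the removed barcodes would have allowed up to 6.54 and 8.42 CPM.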

How the results depend on the processing

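Among the alternatives given here, those on the total of the shares, the unnamed phagocyte cluster, the heat-shock cluster and the weight of clusters were chosen after seeing the data. Of 28 results that answer a comparison and have a direction, 21 kept it under every alternative that gave a value, and of their 348 values 335 did. Among them, 24 had an interval that excluded equality, and 19 of these kept their direction. Of 116 other results, 97 did, and of their 1496 values 1451. These directions are of CPM ratios except under the other scalings. The median gene of macrophages and monocytes had a log2 ratio of 0.12, and directions relative to it were not counted. Some CPM medians of the class lay below 0.12, such as 0.052 for pro-inflammatory myeloid and 0.060 for MHC class II presentation genes. Their directions relative to the median gene are not known. The values that turned, and those that moved beyond their counting interval for a result that answers a comparison, follow, and the cause was not tested. Hypoxia in monocyte, with a median of 0.11, -0.0086 to 0.21, turned under 8 alternatives: -1.72 and -1.12 with mitochondrial limits of 5% and 20%, -0.28 with at least 500 genes, -0.72 with doublets kept, -1.02 and -0.40 at Leiden resolutions 0.5 and 2.0, -0.20 with each library clustered on its own and -0.19 with every cluster weighed the same. Neutrophil granule and maturity in neutrophil, -0.001, -0.24 to 0.26 by CPM, turned to 0.083 under TMM scaling and 0.23 with list members of at least 100 UMIs. The log2 values are of CPM ratios except under the other scalings. On that scale the medians in macrophages and monocytes were pro-inflammatory myeloid 0.26, alternatively activated macrophage -0.58, interferon-gamma response 0.25, type I interferon response -0.30, MHC class II presentation 0.27, chemokines -0.12 and dissociation and early stress 0.052, and tumour neutrophil activation in neutrophil was 0.63. With a mitochondrial limit of 5%, log2 values were cytotoxic effector 0.38, naive and memory 1.41, Gzme -0.70 in CD8 T, dendritic cell maturation 0.12 in dendritic cells, chemokines 0.00014 in macrophages and monocytes, alternatively activated macrophage -1.11, MHC class II presentation -0.21 in monocyte. With a limit of 20%, log2 values were cytotoxic effector 0.44, proliferation -0.50 in CD8 T, dendritic cell maturation 0.13 in dendritic cells, tumour neutrophil activation 0.89 in neutrophil, alternatively activated macrophage -1.09 in monocyte. With at least 500 genes per cell, log2 values were naive and memory 1.17 in CD8 T, dendritic cell maturation 0.12 in dendritic cells, alternatively activated macrophage -0.99, MHC class II presentation -0.068 in monocyte, MHC class II presentation -0.071 in macrophage. With doublets kept, the ratio of shares was gamma-delta T 1.04. There, log2 values were alternatively activated macrophage -0.15, MHC class II presentation -0.070 in monocyte, MHC class II presentation -0.076 in macrophage. At Leiden resolution 0.5, the ratio of shares was CD8 T 0.391, CD8 T per Treg 0.317. There, log2 values were cytotoxic effector 0.64, checkpoint and exhaustion -0.21, naive and memory 0.76, proliferation 0.051 in CD8 T, MHC class II presentation 0.24, chemokines 0.0069 in macrophages and monocytes, alternatively activated macrophage -0.64 in monocyte, Ccl24 -1.72 in Treg. At resolution 2.0, the ratio of shares was gamma-delta T 1.07. There, log2 values were chemokines 0.0056 in macrophages and monocytes, alternatively activated macrophage -0.48 in monocyte. With each library clustered on its own, the ratio of shares was macrophages and monocytes 0.726. There, log2 values were cytotoxic effector 0.46, naive and memory 1.65, proliferation -3.96, Gzmc -0.57, Gzme -0.83 in CD8 T, Treg effector -0.29, proliferation 0.23, Ccl24 -1.90 in Treg, pro-inflammatory myeloid 0.32, alternatively activated macrophage -0.70, interferon-gamma response 0.44, MHC class II presentation 0.66 in macrophages and monocytes, dendritic cell maturation 0.12 in dendritic cells, neutrophil granule and maturity -1.08, tumour neutrophil activation 0.95 in neutrophil, alternatively activated macrophage -0.053 in monocyte, MHC class II presentation 0.30 in nonclassical monocyte. Under median-of-ratios scaling, log2 values were cytotoxic effector 0.45 in CD8 T, pro-inflammatory myeloid 0.14, alternatively activated macrophage -0.70, interferon-gamma response 0.13, type I interferon response -0.42, MHC class II presentation 0.15, dissociation and early stress -0.069 in macrophages and monocytes, dendritic cell maturation -0.12 in dendritic cells. Under TMM scaling, log2 values were cytotoxic effector 0.43, naive and memory 0.88, proliferation -0.67 in CD8 T, pro-inflammatory myeloid 0.13, alternatively activated macrophage -0.71, interferon-gamma response 0.13, type I interferon response -0.42, MHC class II presentation 0.14, dissociation and early stress -0.073 in macrophages and monocytes, dendritic cell maturation -0.15 in dendritic cells. With every cell weighed the same, log2 values were naive and memory 0.55, proliferation -1.23 in CD8 T, pro-inflammatory myeloid 0.10, interferon-gamma response 0.20, MHC class II presentation 0.20 in macrophages and monocytes, dendritic cell maturation -0.19 in dendritic cells, neutrophil granule and maturity -0.33 in neutrophil, Ccl24 -0.37 in Treg. With every cell thinned to 1000 UMIs, log2 values were naive and memory 0.60, proliferation -1.36, Gzme -0.019 in CD8 T, Treg effector 0.18, Ccl24 -0.66, Penk 0.0079 in Treg, pro-inflammatory myeloid 0.052, interferon-gamma response 0.071 in macrophages and monocytes, MHC class I presentation 0.11 in dendritic cells, neutrophil granule and maturity -0.29 in neutrophil. With any UMI, log2 values were pro-inflammatory myeloid 0.31 in macrophages and monocytes. With granulocytes left out of the total, the ratio of shares was macrophages and monocytes 0.718, NK 3.47, CD8 T 0.941. With granulocytes and NK cells left out, the ratio of shares was macrophages and monocytes 0.865, dendritic cells 0.617, CD8 T 1.13, CD4 T 2.30, Treg 1.74. Without the heat-shock cluster, the ratio of shares was macrophages and monocytes 0.712. There, log2 values were MHC class II presentation 0.23 in macrophages and monocytes. With every cluster weighed the same, log2 values were checkpoint and exhaustion -0.11, naive and memory 0.20, proliferation -0.030 in CD8 T, pro-inflammatory myeloid 0.35, alternatively activated macrophage 0.019, interferon-gamma response 0.21, type I interferon response -0.12, MHC class II presentation 0.060, chemokines 0.044 in macrophages and monocytes, dendritic cell maturation 0.18, proliferation 0.18, Top2a 0.10, Pclaf 1.28, Cadm1 1.01, Stmn1 1.44, Tlr3 0.038, Itgae 0.10 in dendritic cells, MHC class II presentation -0.11 in macrophage. In that weighing cDC1 were left out for too few cells, which by construction takes their genes out of dendritic cells. The heat-shock cluster M5 was left out of macrophages and monocytes for the same reason. Log2 ratios of named genes that an alternative moved by over 1.5 times ranged over the alternatives as follows: Ace 0.40 to 1.79, Adgre4 0.41 to 1.82, Ccl24 -2.69 to -0.79, Ccl7 -1.94 to -0.76, Dmkn -2.22 to -1.15, Hbegf -2.58 to -1.01, Hspa1a -3.86 to -2.26, Hspa1b -3.66 to -1.90, Mmp13 -3.67 to -1.74, Mt2 -2.79 to -1.01, Pglyrp1 0.80 to 2.19, Retnla -2.57 to -0.41, Smpdl3b 0.97 to 1.93, Timp1 -2.20 to -0.57 in macrophages and monocytes; Dut -2.30 to -0.59, Gm42031 -2.51 to -0.82, Gzmc -0.57 to 3.06, Gzme -0.83 to 2.46, Hist1h1b -5.85 to -0.78, Hist1h2ae -6.30 to -0.92, Hspa1a -3.09 to -1.43, Hspa1b -2.66 to -1.49, Il1b 1.77 to 3.80, Klf3 0.70 to 2.995, Lmna 0.97 to 2.03, Pde2a 1.24 to 3.15, Xcl1 1.63 to 2.62 in CD8 T; Cadm1 -2.04 to 1.01, Cd33 1.28 to 2.01, Dusp2 0.88 to 1.79, Id3 2.29 to 2.97, Itgae -1.71 to 0.10, Pclaf -2.72 to 1.28, Rnd3 0.67 to 1.85, Spon1 0.94 to 1.82, Stmn1 -2.13 to 1.44, Tlr2 0.86 to 1.67, Tlr3 -1.70 to 0.038, Tnfrsf9 -1.70 to -0.11, Top2a -3.15 to 0.10, Tpm3-rs7 2.34 to 3.26, Xcr1 -2.31 to -0.20 in dendritic cells; Ccl24 -1.90 to 2.32, Gm42031 -1.69 to -0.95, Hspa1a -3.69 to -1.72, Hspa1b -3.60 to -1.78, Penk -1.68 to 0.0079, Tpm3-rs7 2.74 to 4.58 in Treg; Hspa1b -3.09 to -2.42 in NK. No value could be had for eosinophils and CD4 T cells with at least 500 genes, for CD4 T cells at Leiden resolution 0.5, or for eosinophils, CD4 T cells and gamma-delta T cells with each library clustered on its own. With a naming minimum of 200 UMIs, 7 of 10 named genes were shared in Treg and all 20 in each other class. Depth limits classes with few cells, among them the neutrophils and eosinophils of the PBS library and the cDC1 of the UDSP-Hep library. No paired analysis was possible because each group had 1 library.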

Other observations

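Of the tests in this part, that of NK cells per other lymphocyte and the scaling up of removed barcodes were chosen after the result was seen, the explanation in the test of S100a8 and S100a9 was narrowed after its result, and the genes that differed in 5 classes and the lists of CD4 T cells were picked from their values, with no alternative computed for those lists. CD4 T cells other than Treg, 83 and 149 cells, had lower type I interferon response genes in the UDSP-Hep library: of 18 measured, 0 counted as higher, 11 as lower and 7 as neither (median log2 ratio -0.74, -0.93 to -0.53). Cytotoxic effector genes went the other way in these cells: of 15 measured, 7 counted as higher, 0 as lower and 8 as neither (median 1.09, 0.43 to 1.41). Summed markers in them were 10.6 and 32.0 CPM for NK cells and 7.94 and 94.5 CPM for neutrophils. Ifit1, an interferon-induced gene, stood at 161 and 65.5 CPM (ratio 0.406, 0.268 to 0.610).

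Across macrophages and monocytes, dendritic cells, NK cells, CD8 T cells and Treg, 6 genes had a CPM ratio of at least 2 in all 5 classes and 2 the inverse. The latter were Hspa1a and Hspa1b. The former were Il1b, S100a8, S100a9, Tnfaip2, Ly6i and Tpm3-rs7. Relative to the median gene, Il1b fell short of 2 in macrophages and monocytes. Over the classes, Ly6i stood at 0.528 to 105 CPM in the PBS and 6.34 to 330 CPM in the UDSP-Hep library. RNA of other cells was not excluded where such myeloid genes were low. S100a8 had 0 UMIs in the NK cells and Treg of the PBS library, so its ratios there are bounds. S100a8 and S100a9 are abundant in neutrophils, and over these classes S100a8 stood at up to 3.83 CPM in the PBS and 19.0 CPM in the UDSP-Hep library and S100a9 at up to 4.06 and 29.1 CPM. Tpm3-rs7 (ENSMUSG00000058126, chromosome 14 from 113314608 to 113316754) stood at 4.23 to 10.6 CPM over the classes of the PBS library and at 71.8 to 84.6 CPM over those of the UDSP-Hep library, and its counts are uncertain because it resembles Tpm3.

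For the larger share of neutrophils in the UDSP-Hep library, loss of PBS neutrophils to the filters used here was argued against, as far as a profile finds them. With removed barcodes that had at least 1% of UMIs from S100a8 and S100a9 counted back (2 of 662 PBS and 45 of 677 UDSP-Hep barcodes), the ratio of shares was 14.2 (10.9 to 18.5), and it was 14.6 with them scaled up for the neutrophils that miss this minimum, which 69.6% and 49.9% of kept neutrophils met. Neutrophils broken open in the PBS suspension as loaded would leave RNA in other cells. S100a8 and S100a9 in T and NK cells were at 2.21 and 31.9 CPM, a ratio of 14.5 (9.41 to 23.3), which argues against breakage at that stage only. Neutrophils lost intact before loading would leave no such RNA. Those broken open before the CD45 sort would leave none either if their RNA was not carried over, so both losses stay open. Barcodes taken out before the counts were made public could not be counted back. The smallest barcode total was 500 UMIs in each library, so a loss of neutrophils below it stays open too. The injections and any other difference between the libraries may each account for the pattern and cannot be told apart with 1 library per group.

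Heat-shock genes were lower in the macrophages and monocytes of the UDSP-Hep library, where the median of 6 such genes was -1.43. The kept PBS cells of the heat-shock cluster had a median mitochondrial share 1.11 (1.05 to 1.17) times that of the other PBS macrophages and monocytes. Cells with a high mitochondrial share had been filtered out beforehand, so this ratio cannot exclude damaged cells, which stay open. Handling of the whole PBS suspension may also have raised these genes. Their medians were -0.66 in CD8 T cells, -0.88 in NK cells and -0.38 in Treg. These were short of the -1 in each that was set for handling and not all above the -0.5 set against it. Outside that test, the 6-gene median was -0.35 in dendritic cells, and Hspa1a and Hspa1b summed had ratios of 0.00770 (0.00398 to 0.0135) in basophils, 0.148 (0.119 to 0.183) in other CD4 T cells, 0.0416 (0.00841 to 0.126) in B cells and 0.803 (0.664 to 0.979) in neutrophils. The B cell ratio rests on 80 and 3 UMIs, in cells whose summed neutrophil markers were 16.7 and 3089 CPM. The injections, untested, and other differences between the libraries stay open as well, since each group had 1 library.

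NK cells were a larger share of the UDSP-Hep library. A smaller share of macrophages and monocytes would raise all lymphocytes alike, but NK cells per other lymphocyte had a ratio of 3.05 (2.65 to 3.51). A loss of cells with few UMIs from the PBS library was argued against by cells with at least 4000 UMIs. Among these, NK cells were 3.69% and 13.8%, a ratio of 3.74 (3.21 to 4.36). A loss by cell size was not tested, since a UMI minimum does not select on size. The injections and other differences between the libraries may each account for it and cannot be told apart with 1 library per group.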
